A study of Mus musculus with 4 samples.

How the data were processed

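Total liver RNA of 8 male mice of a mixed strain, each 2 months old, was measured on 4 mouse gene expression arrays of the Agilent 4x44K design. Each array carried RNA of 1 control mouse and 1 mouse with a conditional knockout of NIPP1 in the liver, labelled with different dyes. Per the labels, the knockout RNA carried Cy3 on replicates 1 and 2 and Cy5 on replicates 3 and 4, so the dyes were balanced over the 4 arrays, and each dye orientation held different mice. No mouse was measured on more than 1 array. NIPP1, encoded by Ppp1r8, is a nuclear regulatory subunit of protein phosphatase 1. The Cre line and the deleted exons are not given in the sources used here.

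Per the labels' protocols, RNA was spiked with viral control transcripts, converted to cDNA, amplified as cRNA and labelled with Cy3 or Cy5. Per the file headers, the scanner software was Agilent Feature Extraction 10.7.3.1, and the deposited files hold, for each spot and dye, the mean pixel intensity, the median intensity of the local background and flags set by the software. The deposited files also hold processed intensities, which the software had background-subtracted, detrended and dye-normalized per the file headers, and the log10 ratio of processed Cy5 over processed Cy3. The log10 ratios were not tested. The value table deposited by the authors holds log2 ratios. On each of the 4 arrays all 43020 of its values lay within 0.0001 of log2 knockout over control computed from the processed signals, so its scale and direction were known and no centring had been added. Its column medians were -0.05, 0.14, -0.18 and -0.18 for replicates 1 to 4.

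Each array had 44397 spots, of which 43020 were not controls. Of these spots 30708 matched a RefSeq accession in the gene table used for current symbols, the others kept the symbol of the array design, and 6273 had no gene name. Probe positions are those of the array files on the mouse build mm9. No spot was saturated on any array. The median Cy3 signal was 60.6 to 62.4 against a median local background of 23, and the median Cy5 signal was 125 to 126 against 64 to 68. Between 52.7% and 55.3% of spots were well above background in Cy3 and between 54.7% and 56.3% in Cy5. The number of arrays limits the precision.

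Local background was corrected with normexp and an offset of 50, its parameters fitted on every spot of an array, and ratios were normalized within arrays by loess with control spots at weight 0. Control spots and spots with a feature outlier mark of the scanner software (194 to 230 per array) were then left out. Spots of a probe were averaged. A probe was tested if it was well above background in at least 3 mice of 1 genotype. Of the probes of a gene, the one with the highest average intensity stood for the gene, and probes without a symbol were kept on their own. This left 20815 probes and 16304 genes. Among 3679 genes with several tested probes, 5 had probes of opposite sign that both passed an adjusted p of 0.1.

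The fit was made in limma 3.58.1 under R 4.3.3, with the ratio of an array as the unit (n = 4), a dye intercept and the knockout effect signed by its dye. All p-values are two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05. Because of the dye intercept, a gene whose arrays agree within each dye orientation can reach a low p where the orientations differ in sign. The standard errors likewise leave out any difference between the orientations. Values of single arrays are therefore given for several such genes and lists. Gene lists were tested with camera at a preset correlation of 0.01 between genes, with adjustment over the 51 lists that had at least 5 tested members. The estimated correlation and fry were used as alternatives. Fry used statmod 1.5.0, files were read with data.table version 1.17.8, and figures were drawn with matplotlib 3.10.9.

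The gene lists, the model, the threshold and the rule for named genes were fixed before the data were examined. The rule names Ppp1r8 and a fixed set of markers (Afp, Sox9, Krt7, Krt19, Epcam, Spp1, Cd24a, Alb, Hnf4a, Cyp7a1, Mki67, Cdkn1a, Ezh2, Eed, Melk and Col1a1). It then names the 10 genes per direction with the largest log2 change among those past the threshold that have the same sign on all 4 arrays, are well above background in at least 3 mice of the brighter genotype and have no clone or model name. Of each called list it names up to 4 members past the threshold in the direction of the list, and of each other list up to 2. No gene passed 0.05, so the same rule was applied at an adjusted p of 0.1, a choice made after that count was seen. Melk had no tested probe. Genes named beyond the rule are said to be so in the text.

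On replicate 1 the normexp fit went wrong. Its fitted background means were -273 in Cy3 and -185 in Cy5, against 4.44 to 5.76 and -15.7 to -12.4 on the other arrays. Replicate 1 held 8 Cy3 spots more than 20 units below their local background, all 8 with a mark for non-uniform background, and its highest local background in Cy3 was 11207 against 34 to 46 on the others. The fit was kept as fixed. A repaired fit estimated the parameters without spots carrying a background outlier mark, applied them to every spot and left out spots of non-uniform background. It gave means of 4.26 and -9.86 on replicate 1. The repaired fit, its combinations with other choices, other offsets and 2 combinations with no dye term were added after the data and other counts of calls had been seen.

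The alternatives fixed beforehand were the processed signals, the deposited table, no background correction, median centring in place of loess, Aquantile between arrays, no filter, a filter on all 8 channels, no dye term, the mean of the probes of a gene, outlier marks kept, eBayes with trend and robust, separate channels (intraspot correlation 0.41), an adjusted p of 0.1, a fold of at least 2, and leaving out each replicate in turn. Aquantile left the ratios unchanged, the deposited table repeats the processed signals, and a fold filter cannot add genes. They are therefore not separate checks, though counts over the 12 other planned settings include Aquantile and the deposited table. In the added fits with trend and robust and no dye term, the smallest adjusted p of limma was 1.2e-157, and 1.8e-284 when repaired. Values this small are not credible from 4 arrays, so calls of these fits carry little weight. All 4 arrays lay on 1 slide and came from 1 scan, so neither could be tested as a batch.

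The gene fit was tested on simulated data with 16304 genes, in 20 simulations with 200 changed genes each. Variances were drawn at random from the prior fitted to this experiment, not taken gene by gene. At an adjusted p of 0.05 it found on average 89.8 of 100 genes changed by 1 on the log2 scale and 98.6 of 100 changed by 2, with 9.5 false calls. A list shifted by 0.5 was found in 20 of 20 simulations with independent genes. The simulated errors were normal and independent, and no array had failed. These rates therefore need not hold for the real arrays, and they do not show that few genes changed.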

Results

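Gene expression was compared between livers of 4 mice with a conditional liver knockout of NIPP1 and 4 control mice, to ask which transcripts differ when this regulator of protein phosphatase 1 is removed from the liver. Knockout and control RNA shared each of 4 two-colour arrays, and the 8 mice were all different. All values are log2 knockout over control, and errors are standard errors of the fit unless stated otherwise. Such errors leave out any difference between the dye orientations, which held different mice. Between 52.7% and 56.3% of spots were well above background, depending on array and dye. Genome positions are on mm9.

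Ppp1r8, the targeted gene, had less signal in the channel labelled knockout on each of the 4 arrays. Its brighter probe, at chromosome 4, 132383193 to 132383252, gave a log2 ratio of -0.57 ± 0.27 (SD, n = 4), with -0.18, -0.73, -0.74 and -0.63 on replicates 1 to 4. A second probe at 132383814 to 132383873 gave -0.53 ± 0.23 (SD, n = 4). Both probes were well above background in all 8 channels. In limma the brighter probe had a standard error of 0.10 and an adjusted p of 0.106, which missed the threshold. In the scanner software's processed signals the second probe was the brighter and had -1.22 ± 0.08 with an adjusted p of 0.0644 in limma, while the first had a mean of -1.33. A separate-channel limma fit gave an adjusted p of 0.00822. Whether the probes lie in the deleted part of the gene is not given in the sources used here.

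**Figure D1:**
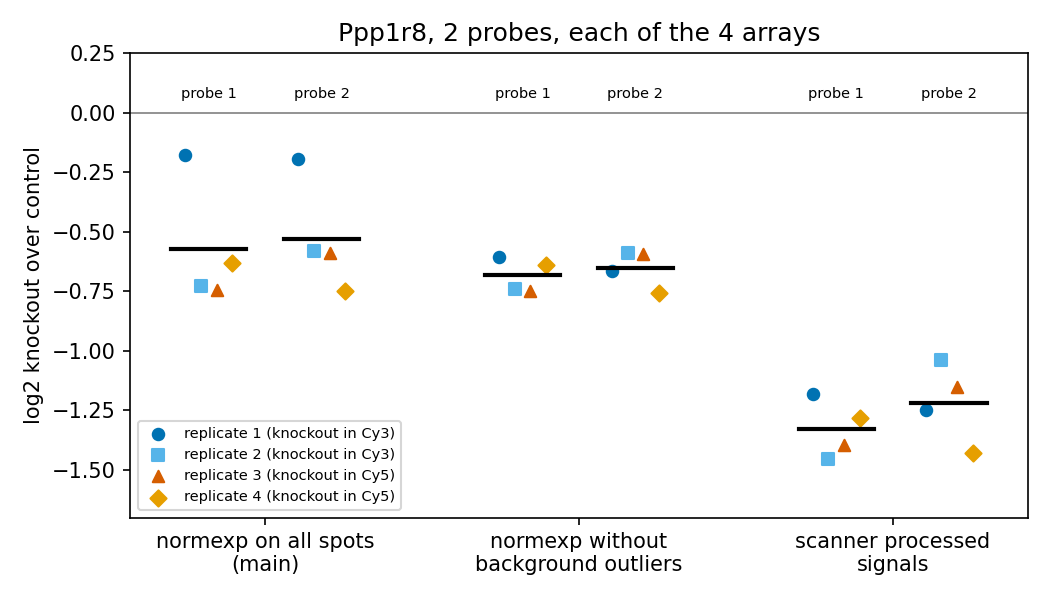
Log2 knockout over control of the 2 Ppp1r8 probes (vertical axis) on each of the 4 arrays, under 3 ways of treating the background; points are arrays, coloured by replicate and named with the dye of the knockout, and bars are means. All points lie below 0. Replicate 1 lies at -0.18 and -0.20 with normexp fitted on all spots, and at -0.61 and -0.67 with the repaired fit.

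No gene passed an adjusted p of 0.05 in either direction among 16304 tested with limma: 0 were higher and 0 were lower, and the smallest adjusted p was 0.0648. At an unadjusted p under 0.05 there were 3549 genes, 1782 higher and 1767 lower in the knockout, where 815 would come by chance; the dye term of the same fit had 3405. At an adjusted p under 0.1, 244 genes were higher and 198 lower, 392 of these 442 with the same sign on all 4 arrays. That count fell to 0 with median centring and to 16 with no dye term, and rose to 680 with the processed signals. Over all tested genes 23.2% had the same sign on all 4 arrays, against 12.5% by chance. The planned separate-channel fit, which uses the intensities of each dye rather than ratios, called 1255 genes higher and 1154 lower at 0.05, and the processed signals called 5 higher and 3 lower. Correlations between arrays across genes, which are not independent replicates, ran from 0.52 between replicates 3 and 4 to -0.28 between replicates 1 and 4.

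The 10 largest positive differences named here are those at an adjusted p under 0.1 with the same sign on all 4 arrays, as the naming rule asks. Col5a3, a type V collagen chain probed at chromosome 9, 20574592 to 20574651, had a log2 ratio of 2.32 ± 0.15 (limma adjusted p 0.0648). Cd36, a fatty acid receptor, had 1.90 ± 0.26, and Mogat1, an acyltransferase that makes diacylglycerol, had 1.70 ± 0.19. Asns, which makes asparagine, had 1.80 ± 0.26, Vnn1, a pantetheinase, had 1.61 ± 0.18, and Gstp3, a glutathione transferase, had 2.04 ± 0.27. Dmbt1, a secreted glycoprotein of epithelia, had 2.01 ± 0.23. The receptor gene Mas1 (1.70 ± 0.27), the transporter gene Slc22a26 (1.60 ± 0.25) and Npb, which encodes neuropeptide B (1.60 ± 0.09), completed the 10. Slc22a26 ranged from 0.07 on replicate 1 to 2.86 on replicate 3, and Gstp3 from 0.49 on replicate 3 to 3.58 on replicate 2. On replicate 1, where the background fit failed, each of the 10 had a larger value with the repaired fit. Mas1 had 2.38 there against 1.35, and Slc22a26 0.24, or 0.55 with the processed signals. Ranges that include replicate 1 are therefore not differences between mice alone. With the processed signals the order changed, and Slc22a26 (3.28), Mogat1 (2.82) and Dmbt1 (2.60) lay above Col5a3 (2.58), with Mas1 at 2.53.

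The largest negative differences, chosen in the same way, were smaller. Hspb1, a small heat shock protein probed at chromosome 5, 136365366 to 136365425, had a log2 ratio of -1.61 ± 0.08 (limma adjusted p 0.0648), and Crlf2, a cytokine receptor subunit, had -1.31 ± 0.05. The murinoglobulins Mug1 and Mug2, close relatives whose probes may not be fully specific, had -1.24 ± 0.13 and -1.23 ± 0.14. Csad, an enzyme of taurine synthesis, had -1.13 ± 0.07, Car1, a carbonic anhydrase, -1.06 ± 0.07, and Slco1a1, an organic anion uptake transporter, -1.02 ± 0.10. Serinc2 (-1.28 ± 0.13), Cdpf1 (-1.13 ± 0.07) and Slc7a4 (-1.06 ± 0.17) completed the 10. On replicate 1 the repaired fit gave -1.84 for Cdpf1 against -0.98, and -1.42 for Slc7a4 against -0.68. Slco1a1 went the other way, with -0.30 against -0.36. Of these 20 genes only Serinc2 passed 0.05 with the processed signals (log2 -1.96, limma adjusted p 0.0391), where Cdpf1 and Slc7a4 each had -1.75. Leaving out replicate 1 left 59 genes at an adjusted p under 0.1, 25 of them among the 442, and leaving out replicate 2, 3 or 4 left 0. A fit of the remaining arrays with a dye term has few degrees of freedom, so lost power alone can bring fewer calls.

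**Figure D2:**
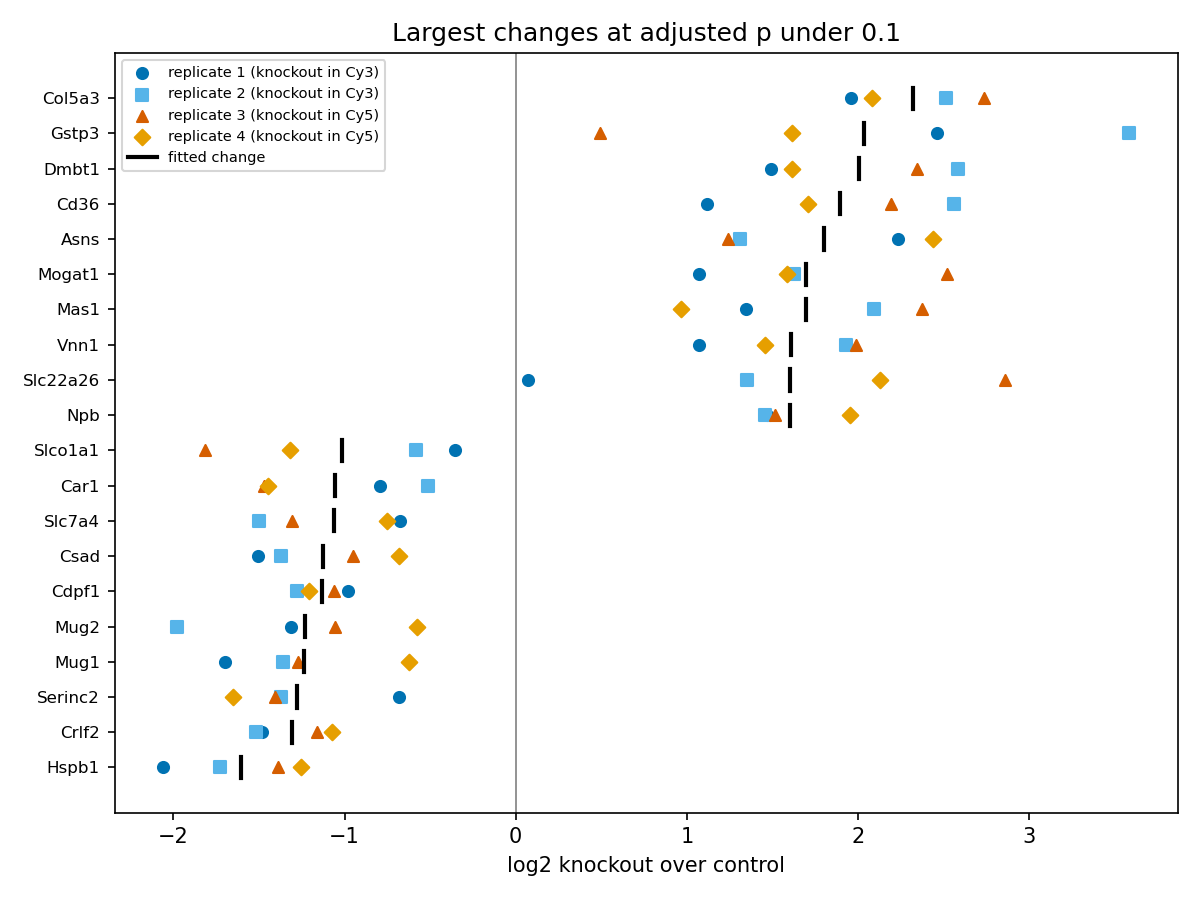
Log2 knockout over control (horizontal axis) of the 10 genes with the largest positive and the 10 with the largest negative change at an adjusted p under 0.1, among genes chosen for having the same sign on all 4 arrays; points are the 4 arrays and bars the fitted change, from Col5a3 at 2.32 to Hspb1 at -1.61. Points of replicate 1 come from the background fit that failed there.

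Of 51 gene lists tested with camera at a preset correlation, 8 were called higher and 3 lower in the knockout, and 40 were not called. With an estimated correlation none of the 51 was called (smallest adjusted p = 0.971 with an estimated correlation), and fry, which asks whether the genes of a list move 1 way, called 0 (smallest adjusted p 0.0956). Fry's test for change in either direction called 17. It does not compare a list with the other genes, and 3549 of 16304 genes had an unadjusted limma p under 0.05. A call by it need therefore not be particular to a list. No member of any list passed 0.05 over all genes; adjusted over the list alone, 105 list entries did. Only 4 of the 11 called lists, those of lipid droplet proteins, biliary cells, complement and coagulation factors and NRF2 targets, had medians of the same sign on all 4 arrays. The biliary median was only 0.003 on replicate 1. With the repaired fit the p53 targets also had positive medians on all 4 arrays, from 0.048 to 0.16.

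Lipid droplet proteins were the list with the lowest p. Of the 12 tested, 11 had positive values, with a median of 0.22 (camera adjusted p 0.000121; adjusted p = 0.971 with an estimated correlation), and 5 passed when adjusted over the list alone. The median was 0.42 with the processed signals. Mogat1 had 1.70, Fitm1, which helps to form lipid droplets, 1.56 ± 0.10, G0s2, an inhibitor of adipose triglyceride lipase, 1.42 ± 0.21, and Hsd17b13, a droplet-bound enzyme, 0.58 ± 0.05 in its brighter probe and 0.054 in its other. Fatty acid synthesis genes were called higher too, with a median of 0.31, 13 of 18 above 0 and 4 past the threshold adjusted over the list alone (camera adjusted p 0.0187; adjusted p = 0.971 with an estimated correlation). Elovl6, a fatty acid elongase, had 0.82 ± 0.09 and Fads1, a desaturase, 0.37 ± 0.05. Array medians of the fatty acid synthesis genes were 0.009, -0.28, 0.53 and 0.38 on replicates 1 to 4. Their call was lost without replicate 1 (camera adjusted p 0.34, median 0.26) and with median centring (0.0806, median 0.18).

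The list of female-biased liver genes was called higher, and all 11 tested members were above 0, with a median of 0.89 (camera adjusted p 0.00047; adjusted p = 0.971 with an estimated correlation). Adjusted over the list alone 5 passed; Hao2 had 1.65 ± 0.36, Acot3 1.39 ± 0.29, Cyp2a4 1.39 ± 0.25 and Prlr, the prolactin receptor, 0.79 ± 0.14. These 4 were chosen after their values were seen, since none passed 0.1 over all genes. The list's array medians were 1.09, 1.24 and 1.31 on replicates 2 to 4 and -0.15 on replicate 1. The male-biased genes, not called (camera adjusted p 0.0693), had a median of -0.27, with 11 of 13 below 0. They were called lower with median centring (camera adjusted p 3.9e-06), with no background correction, with no filter, and without replicate 1 or 4. With a replicate left out their median lay between -0.56 and -0.05. Their array medians were 0.48 on replicate 1 and -0.27, -0.83 and -0.65 on the others. Among them Hsd3b5 had -1.23 ± 0.33 and Elovl3 -1.11 ± 0.30, both named after their values were seen.

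Biliary and progenitor cell markers were called higher, with a median of 0.13 and 15 of 17 above 0 (camera adjusted p 0.00047; adjusted p = 0.971 with an estimated correlation), and 6 passed when adjusted over the list alone. Dmbt1 had 2.01, Tspan8, a tetraspanin of epithelia, 0.61 ± 0.07 and Krt19, a keratin of bile ducts, 0.61 ± 0.10, while Krt23, named after its value was seen, had 1.36 ± 0.31. The other biliary genes fixed beforehand were nearer to 0. Spp1, or osteopontin, had 0.33 ± 0.06 (limma adjusted p 0.107), Cd24a 0.24 ± 0.08, Krt7 0.13 ± 0.06 and Epcam, well above background in 1 of 4 control mice, 0.091 ± 0.06. Sox9, a progenitor transcription factor, had -0.17 ± 0.13 (limma adjusted p 0.485). With the processed signals the list median was 0.40, Tspan8 had 1.69, Krt19 0.90, Cd24a 0.61 (limma adjusted p 0.0893), Krt7 0.47, Epcam 0.42, Spp1 0.40 and Sox9 -0.37. Markers of pancreatic acinar cells, a second epithelium that a liver sample can carry, had medians of 3.15, -2.59, -0.16 and -1.02 on replicates 1 to 4.

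Targets of p53 were called higher, with a median of 0.10, 14 of 19 above 0 and 2 past the threshold adjusted over the list alone (camera adjusted p 0.0187; adjusted p = 0.971 with an estimated correlation). Aen, a nuclease, had 0.68 ± 0.08 and Ccng1, a cyclin, 0.44 ± 0.06, whereas Cdkn1a, the inhibitor of cyclin-dependent kinases, had 0.58 ± 0.16 (limma adjusted p 0.16) and was below 0 on replicate 3. The NRF2 and glutathione genes were also called higher, with a median of 0.29 and 14 of 19 above 0 (camera adjusted p 0.0187; adjusted p = 0.971 with an estimated correlation). Adjusted over that list alone, 10 were higher and 4 lower. No NRF2 target passed 0.1 over all genes; Nqo1, a quinone reductase, had 0.63 ± 0.13 and Hmox1, a haem oxygenase, -0.27 ± 0.07, both named after their values were seen. Without replicate 4 the p53 list missed the threshold (camera adjusted p 0.0591, median 0.13), and with median centring the NRF2 list did (0.147, median 0.18).

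Hepatocyte secreted proteins and cholesterol synthesis genes were called higher, and interferon-stimulated genes lower, while the sign of their medians differed between dye orientations. Secreted proteins had a median of 0.08, with 16 of 25 above 0, 8 higher and 1 lower adjusted over the list alone (camera adjusted p 0.0187; adjusted p = 0.971 with an estimated correlation). Their array medians were -0.19 and -0.23 on replicates 1 and 2 and 0.45 and 0.46 on replicates 3 and 4, and median centring turned the list median to -0.11. The call was lost with processed signals (camera adjusted p 0.237), no background correction (0.249), median centring (0.896), no dye term (0.13), and trend and robust (0.0552), and without replicate 1 (0.0902) or 4 (0.109). The list median was 0.15 without replicate 1 and 0.10 without replicate 4. Apoa4, an intestinal and hepatic apolipoprotein, had 1.47 ± 0.16 and was positive on 4 arrays; Apoc2 had 0.64 ± 0.10, and Alb, or albumin, had 0.48 ± 0.05 with -0.29, -0.25, 1.20 and 1.24 on replicates 1 to 4. Apoe had 0.36 ± 0.06 and was positive on replicates 3 and 4 only. With the processed signals both were positive on all 4 arrays. Alb then had 0.003, 0.16, 0.89 and 0.79 on replicates 1 to 4, and Apoe 0.12, 0.03, 0.72 and 0.47. Cholesterol synthesis genes had a median of 0.14, with 19 of 23 above 0 and 3 past the threshold adjusted over the list alone (camera adjusted p 0.0141; adjusted p = 0.971 with an estimated correlation). Lss, lanosterol synthase, had 0.59 ± 0.07, with -0.09 and -0.26 on replicates 1 and 2 and 1.19 on replicate 4. The cholesterol call was lost with median centring (camera adjusted p 0.242), with no dye term (0.13), and without replicate 1 (0.0902) or 3 (0.55). The list median was 0.020 with median centring, 0.077 without replicate 1 and 0.009 without replicate 3.

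Interferon-stimulated genes had a median of -0.27, with 17 of 20 below 0, and adjusted over the list alone 12 were lower and 1 higher (camera adjusted p 0.000192; adjusted p = 0.971 with an estimated correlation). Ifi27l2a had -0.50 ± 0.05, Rtp4 -0.43 ± 0.05, Irf7, a transcription factor of the interferon response, -0.33 ± 0.05 and Ifit1 -0.31 ± 0.05. The list's array medians were 0.14, 0.05, -0.64 and -0.54, so the negative values came from replicates 3 and 4, which carry the knockout in Cy5. With the repaired fit the median of replicate 1 was 0.40. Irf7 and Ifit1 then missed an adjusted p of 0.1 (limma 0.147 and 0.153). They also missed it with the processed signals, at -0.45 and -0.54 (limma adjusted p 0.16 and 0.195). Complement and coagulation factors were called lower, with a median of -0.19, 21 of 29 below 0 and 5 past the threshold adjusted over the list alone (camera adjusted p 0.0129; adjusted p = 0.971 with an estimated correlation). F11, coagulation factor XI, had -0.76 ± 0.11 and C8a, a subunit of the membrane attack complex, -0.64 ± 0.10 in its brighter probe and -0.29 in its other. Endothelial cell markers were called lower with a median of -0.11 and 18 of 20 below 0, and no member passed when adjusted over the list alone (camera adjusted p 0.0475; adjusted p = 0.971 with an estimated correlation). The complement median was -0.35 with median centring and between -0.25 and -0.12 with a replicate left out. Without replicate 3 the complement list missed the threshold (camera adjusted p 0.0541), and the endothelial list missed it without replicate 1 (0.187) or 3 (0.239) and with the processed signals (0.0556), among other settings. The endothelial median was -0.07 without replicate 1, -0.06 without replicate 3 and -0.13 with the processed signals.

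**Figure D3:**
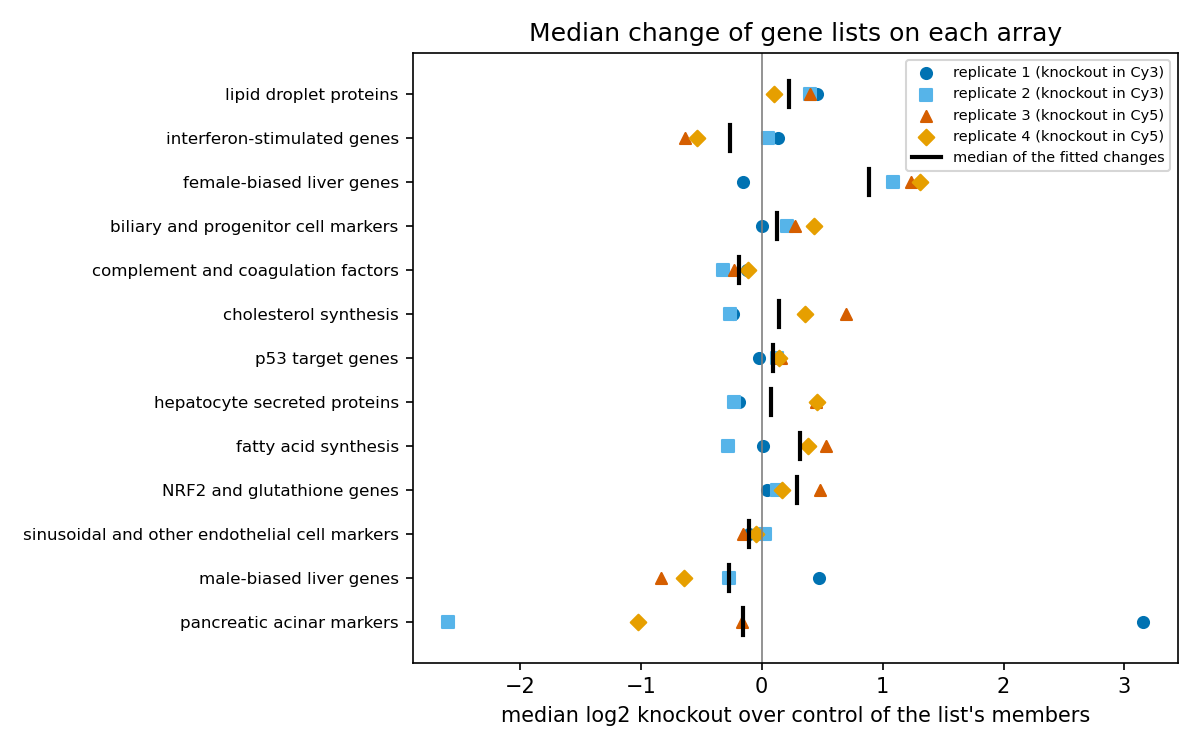
Median log2 knockout over control (horizontal axis) of the members of the 11 called gene lists, of the male-biased genes and of the pancreatic acinar markers on each of the 4 arrays (points), with the median of the fitted changes (bars). Female-biased genes lie near 1 on replicates 2 to 4 (1.09 to 1.31) and at -0.15 on replicate 1, and acinar markers run from -2.59 to 3.15.

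The lists of cell cycle genes, Polycomb components and hepatocyte transcription factors were not called by camera. G1/S phase genes had a median of 0.01 and G2/M phase genes of -0.04, and Mki67, a proliferation marker, had -0.11 ± 0.15 (limma adjusted p 0.721). Polycomb components, some of which are known partners of NIPP1, had a median of -0.04 (camera adjusted p 0.366); Ezh2 had -0.06 ± 0.05 and Eed -0.05 ± 0.07. Hox cluster genes had a median of -0.03 over 6 tested members, and developmental transcription factors under Polycomb 0.02 over 13. Spliceosome genes had a median of -0.04 and DNA damage repair genes of 0.02. Fry's test for change in either direction called the spliceosome genes (adjusted p 0.0172) and the hepatocyte transcription factors (0.011). Hepatocyte transcription factors had a median of 0.03, with Hnf4a at -0.08 ± 0.05 and Atf5, a stress-responsive factor, at 0.61 ± 0.05. Atf5 had 0.20 and 0.17 on replicates 1 and 2 and 1.12 and 0.96 on replicates 3 and 4. Fetal liver genes had a median of 0.01, though Afp, alpha-fetoprotein, had -0.43 ± 0.07 (limma adjusted p 0.0957) and was below 0 on 4 arrays. With the processed signals Afp had -0.74 (limma adjusted p 0.0678). Of 23 extracellular matrix genes 11 were above 0 and 12 below, with Col1a1 at 0.04 ± 0.11. Bile acid synthesis genes had a median of -0.06, and Cyp7a1, the rate-limiting enzyme of that pathway, had -0.15 ± 0.32 (limma adjusted p 0.815), from -1.35 on replicate 1 to 0.99 on replicate 4.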

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

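The test on further acinar genes and the test on the control mouse of replicate 1 were set down before their values were seen; the other tests weighed here, and the counts over other sign assignments, were chosen after the results they bear on were known.

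Among 116 named genes and gene lists, 6 had 1 array far from the other 3, where 5.8 would come by chance. Ccng1, a p53 target, had a log2 ratio of 0.23 on replicate 1 against 0.51, 0.51 and 0.52 on the others, and 0.47 on replicate 1 with the repaired fit. G0s2 had 0.40 on replicate 1 against 1.62 to 1.87, and 0.54 on replicate 1 with the repaired fit. Npb had 1.96 on replicate 4 against 1.46 to 1.51, though replicate 1 had 1.89 with the repaired fit. The list of glycolytic isoforms of non-hepatocyte cells had a median of 0.13 on replicate 4 and at most 0.00 elsewhere. The T and NK cell markers had a median of 0.068 on replicate 4 and between -0.08 and -0.11 on the others. The list of female-biased liver genes had -0.15 on replicate 1 and is weighed below. Outside the main measurement, the 10 spike-in control probes of viral E1A transcripts had a median log2 Cy5 over Cy3 of 5.09, between 4.82 and 5.24 on each of the 4 arrays, whichever dye carried the knockout.

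Pancreatic acinar markers, fixed as a list beforehand, had medians of 3.15 on replicate 1 and -2.59 on replicate 2, with 12 of 13 above 1 on the former and 12 of 13 below -1 on the latter. Both arrays carry the knockout in Cy3, so medians of opposite sign, -2.59 against 3.15, argue against a dye bias and against an effect of the knockout itself. Of 20 further acinar genes written down for this test 9 were measured, and their medians were 2.33 on replicate 1 and -2.22 on replicate 2. Of the 9, 6 lay above 1 on replicate 1 and 6 below -1 on replicate 2. Amy2a5, Klk1 and Tmed6 did not, with 0.99, 0.93 and 0.08 on replicate 1 and -0.20, -0.41 and 0.31 on replicate 2. Pancreatic RNA in the knockout sample of replicate 1 and in the control sample of replicate 2 may therefore account for these values. Pnlip and Cpb1, which are abundant in pancreas, had 3.83 and 3.87 on replicate 1. Both are members of the fixed list, so they add no separate evidence. On replicate 4 the list had a median of -1.02 and the further acinar genes -0.85, and whether its control sample carried such RNA as well was not tested. How such RNA could have reached a liver sample was not tested.

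Female-biased liver genes had medians of 1.09, 1.24 and 1.31 on replicates 2 to 4 and -0.15 on replicate 1. Exchanged labels on replicate 1 are argued against by Ppp1r8, whose higher probe there had -1.18 in the processed signals. Xist was well above background in 0 of 8 channels. All mice were labelled male, so no channel shows that the Xist spots can detect its RNA. A female mouse is therefore not settled by this test. The failed background fit is argued against as well, since the median was -0.49 with the repaired fit. The control mouse of replicate 1 lay 0.57 above the highest of the other 3 control mice, whose range was 0.19, so a control mouse with more female-biased RNA is a candidate explanation. The knockout mouse of replicate 1 also had a lower level (-0.09) than the other knockout mice (0.32 to 0.86). The control mouse alone may therefore not account for the list's median there. An effect of the knockout that varies between mice stays open and untested. These levels of single mice came from the background fit that failed on replicate 1. They were not remade with the repaired fit, so they cannot decide between the explanations left.

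Interferon-stimulated, cholesterol synthesis and secreted protein genes had medians of opposite sign in the 2 dye orientations. Their median dye coefficients were -0.33, 0.32 and 0.30 (log2 Cy5 over Cy3). A gene-specific dye bias could give such values, and so could a difference between the mice of replicates 1 and 2 and those of replicates 3 and 4. The 2 cannot be told apart, because no mouse was labelled with both dyes. For Alb and Apoe the sign also depended on the processing, since both were above 0 on every array with the processed signals. Lss and Irf7 still turned sign with those signals. The array medians of the lists were not remade with them. No biological explanation was tested.

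The 4 arrays allow 7 sign assignments that can be fitted beside the dye term, too few for a share under 0.05. At an adjusted p of 0.05 the real assignment gave 0 genes and the highest of the others 0, so all 7 gave as many. At 0.1 the real one gave 442 genes and the highest of the others 0, so 1 of the 7 gave as many. At an unadjusted p under 0.05 the real one gave 3549 genes and the others at most 1007. For gene lists called by camera the real one gave 11 and the highest of the others 18, and 5 of the 7 gave as many.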

How the results depend on the processing

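The repaired background fit, its combinations, the offsets and the 2 added fits with no dye term were chosen after data and counts were seen, the other alternatives beforehand. A result counts as reversed where its sign turned and it passed 0.05 in either setting; the cause of the differences was not tested. Counts are genes higher and lower at an adjusted p of 0.05, 0 and 0 as reported. They stayed at 0 and 0 with median centring, the filter on all 8 channels, no dye term, the mean of probes and outlier marks kept. They also did with every replicate left out in turn and the repaired fit alone. Aquantile and a fold of at least 2 were bound to repeat these counts. Counts were 5 and 3 with the processed signals and likewise with the deposited table, 19 and 10 with no background correction, 17 and 11 with no filter, and 16 and 16 with trend and robust. Separate channels gave 1255 and 1154, and an adjusted p of 0.1 gave 244 and 198. Of the added settings, processed signals with no dye term gave 18 and 12. The repaired fit gave 163 and 47 with median centring, 175 and 88 with no filter, and 6 and 4 with no dye term. With trend and robust it gave 254 and, to 2 digits, 1.3e+02. Trend and robust with no dye term gave 1017 and 925, or 1246 and 857 repaired, at p-values too small to trust. The 4 other offsets and their repaired versions gave 0 and 0. At an adjusted p of 0.1, offsets of 0, 1, 10 and 16 gave 0, 0, 74 and 89 genes in all. The repaired fit at 0.1 had 912 genes, of which 423 were among the 442 reported, and 63.2% of the 912 were higher against 55.2% of the 442. Median centring of the repaired ratios raised that share to 76.4%.

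Genes past the threshold with the processed signals, named after their values were seen, were Inpp5j (2.59), Lrrc14b (1.98) and Slc13a4 (1.59) with 2 probes of no gene name, and Cspg5 (-2.78), Serinc2 (-1.96) and Rd3 (-1.63). The 6 higher genes of the repaired fit with no dye term were Col5a3 (2.44), Dmbt1 (2.19), Npb (1.71), Vnn1 (1.69), Fkbp7 (0.98) and Zfp787 (0.93), and the 4 lower genes Serinc2 (-1.44), Dnaja4 (-1.10), 4933438K21Rik (-1.06) and Eml3 (-0.95). Of the 64 named genes other than Ppp1r8, at least 1 passed in 13 of 39 alternatives.

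Ppp1r8 was below 0 in every alternative run. It passed 0.05 with separate channels (-0.57, adjusted p 0.00822), with processed signals and no dye term (-1.22, 0.0435), with trend and robust and no dye term (-0.57, 2.84e-07), and in the repaired fit with median centring (-0.68, 0.046), no filter (-0.68, 0.0381), trend and robust (-0.68, 0.0287), and trend and robust with no dye term (-0.68, 5.7e-28). Over all settings its adjusted p otherwise lay between 0.0512 and 0.452. With a replicate left out its log2 ratio lay between -0.72 and -0.43. An offset of 0 gave -0.82 and the processed signals -1.22, against -0.57 with 50, each for the probe that was brighter in that setting.

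Gene lists called, 8 higher and 3 lower as reported, were 0 and 0 with an estimated correlation and with fry, and 4 and 5 with median centring. Lists called lower were 1 with processed signals and no dye term, 5 with the repaired fit and no filter, 1 with the repaired fit and no dye term, and 1 with trend and robust added to that. With a replicate left out they were 4 to 10 higher and 1 to 7 lower, 5 and 7 without replicate 1. Reversals came only from left-out replicates. The acinar list, with a median of -0.16, was called lower without replicate 1 and higher without replicate 2, at medians between -1.61 and 1.74, and G2/M phase genes lay between -0.090 and 0.13, called higher without replicate 4 in the repaired fit. The lists called higher or lower under each of 12 other planned settings, not counting an estimated correlation, fry and left-out replicates, were those of lipid droplets, female-biased genes, biliary cells, p53 targets, interferon and complement. Over the same 12 settings medians ran from 0.078 to 0.40 for biliary markers, 0.051 to 0.13 for p53 targets, 0.020 to 0.15 for cholesterol synthesis, 0.18 to 0.33 for fatty acid synthesis and 0.59 to 1.37 for female-biased genes.

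All 4 arrays lay on 1 slide, so no slide block was run. Each ratio already pairs a knockout and a control mouse, so no paired analysis was added.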

Other observations

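The tests reported in this part were planned, except that genes were chosen here after their values were seen.

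Several lists that were not called held single genes with larger differences. Among subunits of protein phosphatase 1, of which NIPP1 is one, Ppp1r1b, an inhibitor known as DARPP in neurons, had a log2 ratio of 1.44 ± 0.18 and was positive on 4 arrays (limma adjusted p 0.088), while the list median was -0.02. The basolateral export transporters had a median of 0.08, with Abcb1a, a multidrug exporter, at 0.60 ± 0.07 and at 1.19 with the processed signals. Abcb1a ran from 0.043 on replicate 1 (0.15 with the repaired fit) to 1.10 on replicate 3. Among canalicular and uptake transporters Abcb4, a phospholipid exporter, had 0.38 ± 0.05 and Slco1a1 -1.02. Aldh1b1 and Hsd17b13, of the periportal list, had 0.76 ± 0.07 and 0.58 (0.054 in the other probe of Hsd17b13), and that list had the lowest adjusted p in fry's test for change in either direction (0.00649), with a median of -0.04. The same test called the phosphatase subunits (0.011), the canalicular and uptake transporters (0.0172), the glycolytic isoforms of non-hepatocyte cells (0.011) and the pericentral genes (0.047). It called 17 of 51 lists and does not compare a list with the other genes. Oat, of the pericentral list, had 0.39 ± 0.05, with 0.77 and 0.66 on replicates 1 and 2 and 0.13 and 0.009 on replicates 3 and 4. Tpi1, a glycolytic enzyme, had 0.41 ± 0.05. Igfbp1, an insulin-repressed binding protein, had -1.62 ± 0.32 (limma adjusted p 0.11), and was negative on replicates 1 to 3.

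Markers of other liver cells had small medians. Macrophage markers had -0.09, neutrophil markers -0.07, quiescent stellate cell markers -0.05, B and plasma cell markers -0.05 and erythroid markers -0.12, none of them called. Zap70, a T cell kinase, had 0.65 ± 0.08 and was below 0 on replicate 2 (-0.11). Acute phase proteins had array medians of 0.35 on replicate 1 and -0.27, -0.18 and -0.15 on the others. Not called as reported, this list was called in 1 of 12 other planned settings and in 1 fit with a replicate left out. Its medians over those 12 settings ran from -0.26 to -0.03. Gdf15, a stress-induced cytokine on the p53 list, had 3.62, 1.56 and 2.62 on replicates 2 to 4 and -0.36 on replicate 1. Cyp4a14 had -3.91 on replicate 1 and 1.41, 2.41 and 3.64 on the others.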
